A study of Mus musculus with 14 samples.

How the data were processed

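Signals of 25697 probes on 14 mouse Illumina bead arrays were used, 8 groups of 1 or 2 arrays from C57BL cells as the labels give them. The deposited non-normalized table holds, per the file headers, an unlogged probe signal and a detection p-value for each probe and array, and all of its columns were used. The authors' second deposited table holds normalized intensities on the log2 scale with the same quantiles on every array, and it served only as an alternative. Per the submitters' processing notes, BeadStudio 3.2, RMA and lumi were used on the values, without the order or settings of these steps. Per the labels, total RNA was amplified, with an in vitro transcription of 18 h and a second linear amplification with one of 12 h both described for every sample. Which array received which amplification, the chip of each array and the genome build of the probes are not given in the sources used here.

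Each probe was assigned to the gene listed for it. Of the probes, 23978 had 1 gene, none had several and 1719 had none and were left out, which gave 16593 genes, 4777 of them with more than 1 probe. Signals were corrected for background by a normal-exponential model fitted with the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. A gene was represented by its probe with the highest mean over all arrays, and it was tested when that probe had a detection p under 0.01 on at least 2 arrays, which left 9054 genes. Detection means a detection p under 0.01 throughout. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

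A linear model with a mean for each of the 8 groups was fitted in limma, with 6 residual degrees of freedom, and variances were moderated with a trend on the mean level, for 9.76 degrees of freedom in total. Contrasts gave the means of lines equal weight, with hiEGL as the mean of hiEGL1 and hiEGL2, ESC as that of ESCm and ESCf, and EpiSC as that of EpiT9 and EpiE3. A gene was called when its p-value, adjusted by Benjamini and Hochberg over all genes tested, was under 0.05. SE is the moderated standard error of a log2 difference and SD the spread between arrays. Gene lists were tested with camera, with the correlation between genes of a list set to 0.01 and, as a second version, estimated from the data, both adjusted over the 19 lists with at least 5 measured genes. Where a gene was detected in only 1 of the groups compared, its fold is a lower bound. Where only some arrays of a group detected it, their number is given and the group's mean includes values at background. The bright group's mean was set against the mean, over the dim group's arrays, of the higher of the lowest signal among detected probes and the dim probe's own value, on normalized log2 values.

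The comparisons, the 20 gene lists, the thresholds, the alternatives of processing and the rule for named genes were set before the data were examined. The lists, with their number of measured genes, were core pluripotency (15), naive pluripotency (18), primed epiblast (20), early PGC specification (11), later germline (14), HIF targets other than glycolysis (29), glycolysis (20), HIF pathway components (9), oxidative phosphorylation (44), cell cycle (26), DNA methylation and chromatin (20), imprinted genes (17), gonadal somatic cells (12), blood, endothelium and macrophages (14), fibroblast feeder cells (23), primitive endoderm and trophectoderm (18), immediate-early and heat-shock stress (14), the 2-cell-like state (6), LIF, BMP and PI3K signalling (22) and a sex-linked label check (3), the last too short for a test. Genes were named when among the 8 largest called rises or falls (4 for hiEGL2 against hiEGL1, ESCf against ESCm, EG against PGC11.5 and EG against ESC) with no overlap between the groups' arrays, leaving out clone, locus, predicted and Riken symbols, when on a fixed list of pluripotency, germline and hypoxia genes, or when among the 4 largest called changes of a list. The text names part of the genes that the rule gave, and Hspb1 and Hsp90aa1 besides, as the falls of the stress list. Of the fixed genes, Kit has no probe listed and Prdm1 was not detected on enough arrays. Lists share some genes, among them Lox (HIF targets and fibroblast markers) and Dcn (imprinted genes and fibroblast markers).

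The alternatives were the authors' values, no background correction, scaling of arrays to the same median of probes detected on all arrays in place of the quantile step, no filter, a filter requiring detection on every array of a group, the mean of a gene's probes, the line as a random block, a fit to only the compared arrays, the replicate number as a block, a 2-fold threshold and leaving out each array in turn. Weights for the PGC11.5 arrays were added after the data were seen. The procedure was tested on simulated data in which all arrays of a gene had the same spread, that of the fitted model. For hiEGL against EG there were 9054 genes, of which 200 were changed. It recovered 43.3% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, and 5.59% of its calls were unchanged genes. In the other comparisons 4.71% to 8.23% of calls were unchanged genes, and of 19 lists the 1 that was shifted was called and 0 others. Genes were simulated independently, so this does not test list calls where genes of a list are correlated. Nor was the larger spread between the PGC11.5 arrays simulated, so the shares for comparisons with PGC11.5 leave it out. The estimated correlation reached 0.535 for the fibroblast list.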

Results

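RNA of mouse pluripotent cells and primordial germ cells (PGCs), the embryonic precursors of eggs and sperm, was measured on 14 single-colour Illumina bead arrays. The samples fall into 8 groups. Embryonic germ (EG) cells, which are pluripotent lines derived from PGCs, gave 2 arrays. Embryonic germ-like lines obtained from PGCs cultured in hypoxia gave 2 arrays for line hiEGL1 and 2 for line hiEGL2. Embryonic stem cells (ESC) gave 2 arrays for ESCm and 2 for ESCf, epiblast stem cells (EpiSC) gave 1 array each for EpiT9 and EpiE3, and PGCs of embryos at 11.5 days post coitum (PGC11.5) gave 2. The titles of the ESCm and ESCf samples name embryonic stem cells, whereas a characteristic of the same samples names embryonic germ cells, and the titles were followed. Nothing in the labels places replicates in separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

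Between 29.8% and 45.4% of the 25697 probes were detected per array. The brightest probe reached a signal of 11270 to 17938 on the EG and hiEGL arrays, at least 40718 on the ESC arrays, 26734 and 27441 on the EpiSC arrays and 14621 and 25879 on the PGC11.5 arrays. Both arrays of a group correlated at r = 0.994 to 0.997 across genes, except for PGC11.5 at r = 0.952, where 1236 genes lay at least 2-fold apart. The number of arrays, at most 2 per group, limits the precision of every value.

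Similarity of whole profiles addressed which known cell type the hypoxia-derived lines resembled. The hiEGL arrays were closest to EG cells, with a mean r of 0.844 across the 9054 genes tested, and the nearest array outside their own lines was an EG array for each of the 4. Their mean r was 0.662 with EpiSC, 0.643 with ESC and 0.637 with PGC11.5. EG cells correlated at 0.807 with ESC, 0.746 with EpiSC and 0.711 with PGC11.5. ESC, EpiSC and PGC11.5 arrays were closer to one another, at 0.812 to 0.852, than to the hiEGL arrays. Genes are not independent replicates, and these correlations have no test. EG and hiEGL arrays are also the only ones on their side of the array divide described next, so their nearness cannot be told apart from that shared array difference. The first principal component held 56.7% of the variance and the second 19.3%.

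The EG and hiEGL arrays stood apart from the other 8 arrays in which probes they detected. For Actb, the gene of beta-actin, probe ILMN_2617433 had a mean log2 intensity of 4.43 in EG and 4.43 in hiEGL but 11.96 in ESC, while probe ILMN_1377923 of the same gene had 12.40, 13.30 and 12.37. Probes of Actb also disagreed among the other 8 arrays, as ILMN_2588055 and ILMN_2846865 stood at 5.42 and 5.40 in ESC, 5.02 and 5.06 in EpiSC and 11.49 and 11.73 in PGC11.5. In all, 802 probes were detected on all 8 other arrays and none of the 6 EG and hiEGL arrays, and 47 showed the reverse. Of 2370 genes with several detected probes, the pair of brightest probes gave opposite calls in 2.97% of pairs with both called for hiEGL against EG, 6.37% for hiEGL2 against hiEGL1 and 0.469% for ESCf against ESCm. Comparisons across that divide had 20.6% to 31.4%, and PGC11.5 against ESC had 21.9%. Every gene value below comes from 1 probe, and a gene's direction across the divide can depend on the probe. These genes were chosen after their values were seen.

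**Figure D1:**
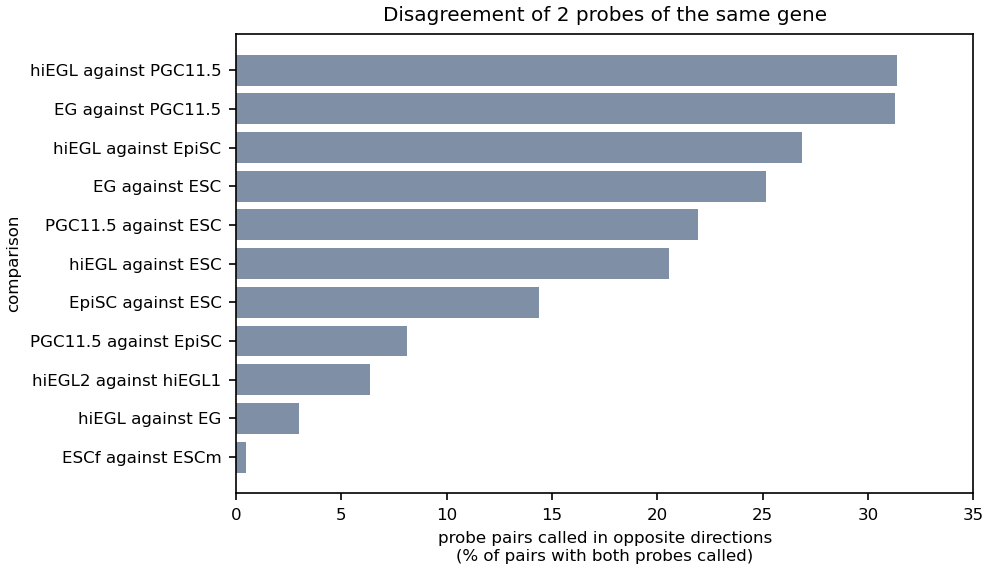
Bars give, for each comparison (vertical axis), the percent of probe pairs of 1 gene called in opposite directions among pairs with both probes called (horizontal axis). The value was 0.469% for ESCf against ESCm and 2.97% for hiEGL against EG, and reached 31.4% for hiEGL against PGC11.5.

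Hypoxia-derived lines were first set against EG cells, their conventionally derived counterpart, to ask what distinguished them, as both start from PGCs. EG is 1 group of 2 arrays, so its difference from hiEGL cannot be told from an ordinary difference between lines. Such differences gave 2713 called genes between hiEGL2 and hiEGL1 and 1747 between ESCf and ESCm. Dlk1, an imprinted gene encoding a transmembrane protein, was at least 79.4-fold higher in hiEGL (log2 intensity 12.13 ± 0.41 in hiEGL and 4.49 ± 0.05 in EG, SD, n = 4 and 2, adjusted p = 3.32e-07). Spon2, a matrix protein gene, rose by 6.24 ± 0.33 (SE) on the log2 scale, or 75.4-fold, and the X-linked homeobox gene Rhox9 rose 68.0-fold. The other largest rises were Ednrb (at least 27.2-fold), Medag (65.5-fold), Ptn (at least 21-fold), Igfbp4 (57.4-fold) and Egr1 (50.8-fold). Dnmt3l, a cofactor of de novo DNA methylation, fell (adjusted p = 5.88e-12) from a log2 intensity of 13.80 in EG. The fall was 6.99 ± 0.10 (SE) on the log2 scale in hiEGL2, and neither hiEGL1 array detected the gene. The other largest falls were Olig1 (at least 33.5-fold), Pla2g1b (at least 19.5-fold), Dnajc6 (at least 21.6-fold), Laptm5 (33.2-fold), Krt42 (at least 14.62-fold), Jam2 (at least 17-fold) and Dmtn (at least 9.76-fold). The largest adjusted p among these genes was 3.68e-05 by limma's test. A fold marked "at least" sets the mean of the detected group against the other group's level or, where higher, the array's lowest signal of a detected probe.

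Pluripotency genes were lower in hiEGL. Of the core pluripotency list, 14 of 15 measured members fell and none rose (camera adjusted p = 0.000115, adjusted p = 0.155 with an estimated correlation), among them Tdgf1 (10.9-fold), L1td1 (4.37-fold) and Gdf3 (3.40-fold). Pou5f1, which encodes Oct4, fell by 1.43 on the log2 scale (adjusted p = 1.54e-06) and was detected on 3 of 4 hiEGL arrays. Its other probe, ILMN_1217100, was detected on all EG and hiEGL arrays and stood at 6.52 in hiEGL and 6.80 in EG. Nanog was 2.21-fold lower, and Sox2, detected on 1 of 4 hiEGL arrays, was 3.8-fold lower. Of the naive pluripotency list, 15 of 18 fell and 1 rose (camera adjusted p = 0.000193, adjusted p = 0.0769 with an estimated correlation), with falls of Manba (14.3-fold), Esrrb (4.83-fold) and Klf4 (3.03-fold) and of Tbx3 (14.2-fold, detected on 2 of 4 hiEGL arrays). Both lists' medians, -1.20 and -1.55, were negative in each hiEGL line as well. The 2-cell-like list, genes of a rare state that recalls the early embryo, had 4 falls and no rise among 6 members (camera adjusted p = 0.0340, adjusted p = 0.240 with an estimated correlation), including Tcstv3 (at least 2.14-fold) and Zscan4c (at least 1.43-fold). Primed epiblast genes were split, with 3 higher and 8 lower of 20 measured (camera adjusted p = 0.221, adjusted p = 0.606 with an estimated correlation). In that list Lefty2 (at least 4.61-fold), Gsc (at least 2.05-fold) and Fgf5 (at least 1.58-fold) fell and Krt8 (6.77-fold) rose.

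Targets of hypoxia-inducible factor (HIF) were higher in the pooled hiEGL lines, whose labels give culture in hypoxia, but as a list only in hiEGL2 when each line was set against EG. HIF targets outside glycolysis had 15 rises and 5 falls among 29 measured (camera adjusted p = 0.0171, adjusted p = 0.155 with an estimated correlation), with a median log2 difference of 0.47. Line hiEGL2 alone was called (17 rises and 4 falls, camera adjusted p = 0.00165, adjusted p = 0.112 with an estimated correlation) and line hiEGL1 was not (11 rises and 7 falls, camera adjusted p = 0.157, adjusted p = 0.350 with an estimated correlation). The carbonic anhydrase gene Car9 was at least 13.3-fold higher, the collagen prolyl hydroxylase genes P4ha1 and P4ha2 were at least 7.55-fold and 10.8-fold higher, Ndrg1 was 5.45-fold higher, and Vegfa, a growth factor of blood vessels, was 3.97-fold higher (log2 difference 1.99 ± 0.13, SE, n = 4 and 2). Glycolysis genes went both ways, 6 up and 6 down of 20 (camera adjusted p = 0.862, adjusted p = 0.898 with an estimated correlation). Their median was -0.00770 and their mean 0.18 on the log2 scale, so that the signs differed. In that list Eno2 (12.3-fold), Pfkfb4 (4.15-fold) and Tpi1 (2.42-fold) rose and Slc2a3 (2.81-fold) fell. Hif1a itself lay below background in both cell types, Epas1 was at least 1.47-fold lower, and the HIF pathway components were not called as a list (1 higher and 2 lower of 9 measured, camera adjusted p = 0.862, adjusted p = 0.898 with an estimated correlation). Oxidative phosphorylation genes were lower, with 28 of 44 down and 4 up (camera adjusted p = 0.00285, adjusted p = 0.294 with an estimated correlation), of which Cox5a (4.82-fold) fell most.

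Genes of DNA methylation and chromatin also fell, 16 of 20 down and 3 up (camera adjusted p = 0.000999, adjusted p = 0.149 with an estimated correlation). Besides Dnmt3l these were led by Uhrf1 (15.3-fold) and Dnmt3b (7.90-fold), the first of which directs maintenance methylation to replicated DNA. Cell cycle genes showed 4 rises and 16 falls among 26 (camera adjusted p = 0.00535, adjusted p = 0.149 with an estimated correlation). The falls included Mcm3 (at least 2.20-fold), Top2a (3.93-fold) and Birc5 (3.67-fold), and the cell cycle inhibitor Cdkn1a (3.28-fold) rose. Early PGC genes gave 6 rises and 2 falls among 11 (camera adjusted p = 0.0340, adjusted p = 0.240 with an estimated correlation), with rises of Dnd1 (5.71-fold), Dppa3 (at least 2.71-fold) and Ifitm1 (4.58-fold). As a list they were called in hiEGL1 (6 rises and 1 fall, camera adjusted p = 0.0197, adjusted p = 0.235 with an estimated correlation) and not in hiEGL2 (4 rises and 2 falls, camera adjusted p = 0.127, adjusted p = 0.265 with an estimated correlation), and Nanos3 was detected on both hiEGL1 arrays and on no hiEGL2 or EG array. Between hiEGL2 and hiEGL1 the list was not called (camera adjusted p = 0.1, adjusted p = 0.473 with an estimated correlation), although it was lower in hiEGL2 without the quantile step (adjusted p = 0.0304) and without the filter (adjusted p = 0.0426). Later germline genes were not called as a list, 3 higher and 5 lower of 14 (camera adjusted p = 0.408, adjusted p = 0.606 with an estimated correlation), although Stra8 (at least 3.2-fold), Taf7l (at least 3.03-fold) and Dazl (at least 1.87-fold) were lower in hiEGL. Imprinted genes had 8 rises and 3 falls among 17 (camera adjusted p = 0.0474, adjusted p = 0.294 with an estimated correlation). Cdkn1c (50.5-fold), Dcn (at least 39.3-fold, also a fibroblast marker) and Igf2 (30.4-fold) rose along with Dlk1. That list was called in hiEGL2 (8 rises and 2 falls, camera adjusted p = 0.0278, adjusted p = 0.258 with an estimated correlation) and not in hiEGL1 (7 rises and 3 falls, camera adjusted p = 0.0668, adjusted p = 0.350 with an estimated correlation), and not for hiEGL2 against hiEGL1 (camera adjusted p = 0.340, adjusted p = 0.706 with an estimated correlation). LIF, BMP and PI3K signalling genes were split, 8 higher and 5 lower of 22 (camera adjusted p = 0.350, adjusted p = 0.371 with an estimated correlation), with Junb (at least 8.82-fold) and Id1 (4.04-fold) up and Etv5 (2.45-fold) down.

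Markers of other cell types and immediate-early genes moved with the hiEGL group beside each of these lists. Fibroblast markers had 20 rises and 1 fall among 23 and a median log2 difference of 1.98 (camera adjusted p = 2.23e-05, adjusted p = 0.294 with an estimated correlation), with Col6a1 (30.5-fold), Timp2 (8.53-fold) and Mgp (at least 5.06-fold). Gonadal somatic markers had 9 rises and 2 falls among 12 (camera adjusted p = 0.0146, adjusted p = 0.149 with an estimated correlation), including Wt1 (at least 6.87-fold) and Sox9 (at least 4.76-fold) and Pdgfra, which was detected on 1 of 2 EG arrays and was 46.7-fold higher. Markers of blood, endothelium and macrophages had 7 rises and no fall among 14 (camera adjusted p = 0.00684, adjusted p = 0.294 with an estimated correlation), with Lyz2 (at least 4.59-fold) and Cd34 (at least 3.47-fold). Primitive endoderm and trophectoderm markers had 12 rises and 1 fall among 18 (camera adjusted p = 0.00302, adjusted p = 0.162 with an estimated correlation), with Col4a2 (10.2-fold), Gata6 (at least 5.08-fold) and Tfap2a (at least 4.36-fold). Immediate-early and heat-shock genes had 11 rises and 2 falls among 14 and a median of 2.93 (camera adjusted p = 0.00535, adjusted p = 0.309 with an estimated correlation). Besides Egr1 the rises included Fos (at least 24.9-fold), Fosb (at least 13.4-fold) and Jun (at least 14.1-fold). Both falls were heat-shock genes, Hspb1 by 2.25 and Hsp90aa1 by 1.69 on the log2 scale.

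In all, 5598 of 9054 genes differed between hiEGL and EG by limma's test, 2571 higher and 3027 lower in hiEGL, and 2766 of them by at least 2-fold. Line hiEGL1 alone had 5323 calls against EG and line hiEGL2 5356. Adjusted over the list alone, the counts differed for later germline (3 higher, 4 lower) and oxidative phosphorylation (5 higher, 28 lower). With the line as a random block the count was 2895, and without the quantile step, where the median of all genes was 0.38, 62.1% of called genes were higher in place of 45.9%. The list test compares a list with the other genes, hence relative to that shift. The early PGC call ended with the line as a random block (adjusted p = 0.117), without the quantile step (adjusted p = 0.0605), without background correction (adjusted p = 0.0672) and with only the compared arrays (adjusted p = 0.0729). The 2-cell-like call ended under the first 3 of these (adjusted p = 0.0916, 0.115 and 0.0544), and that of imprinted genes without background correction (adjusted p = 0.0544) and without EG replicate 2 (adjusted p = 0.0554).

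**Figure D2:**
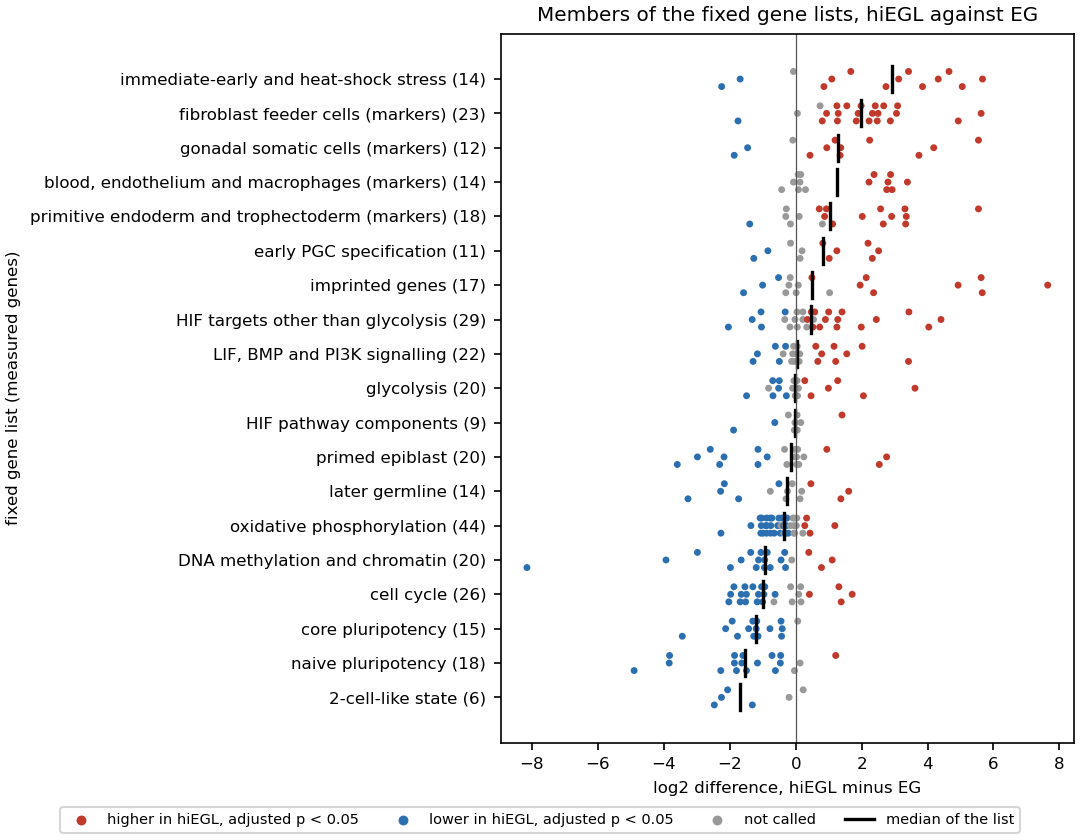
Each point is a measured gene of a fixed list (vertical axis, measured number in brackets), at its log2 difference hiEGL minus EG (horizontal axis), red where called higher, blue where called lower and grey where not called, and black bars mark list medians. Medians ran from -1.69 for the 2-cell-like list to 2.93 for immediate-early and heat-shock genes.

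**Figure D3:**
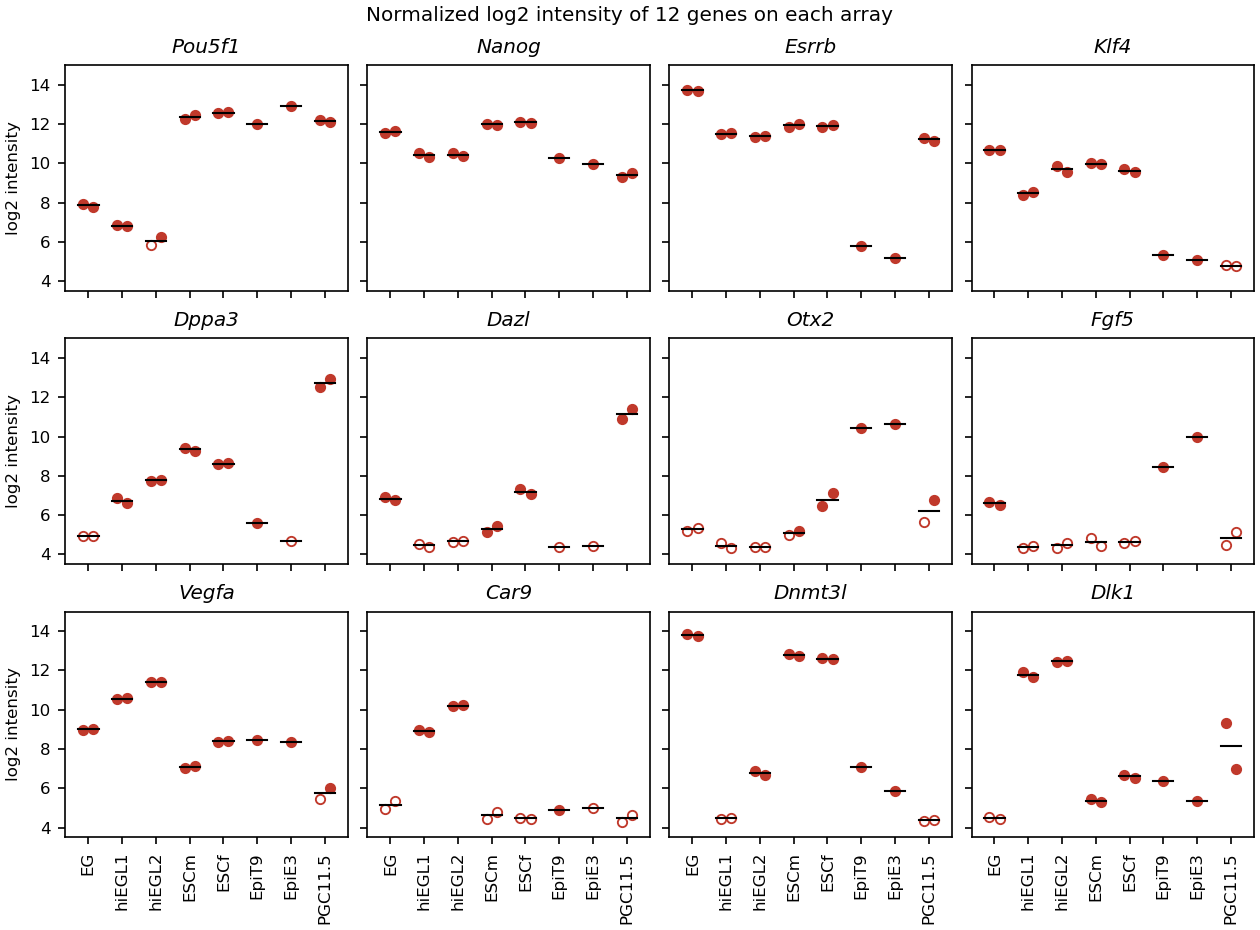
Points are normalized log2 intensities (vertical axis) of 12 genes on each array of the groups named on the horizontal axis, filled where detected and open where not, and black lines are group means. Car9 stood at 9.56 in hiEGL and 5.15 in EG, and Pou5f1 at 6.44 and 7.87 against 12.47 in ESC.

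Both hypoxia-derived lines were then compared with each other to ask how far they differed. Hdc, which encodes the enzyme that makes histamine, was at least 7.09-fold higher in hiEGL2 (8.67 ± 0.10 in hiEGL2 and 5.33 ± 0.06 in hiEGL1, SD, n = 2 and 2, adjusted p = 2.22e-06), and Tff1 (at least 2.69-fold) and Dnmt3l (at least 1.94-fold) rose as well. The Notch target Hes1, detected on 1 of 2 hiEGL1 arrays, was 5.96-fold higher. Lower in hiEGL2 were Chac1 (at least 10-fold), Ubl7 (at least 4.65-fold), Sh3d21 (at least 3.23-fold) and Crtac1 (at least 4.12-fold), the first with a log2 difference of -3.53 ± 0.15 (SE, adjusted p = 1.42e-06). HIF targets outside glycolysis had 13 rises and 2 falls among 29 (camera adjusted p = 0.000318, adjusted p = 0.118 with an estimated correlation), with Lox (3.95-fold), Kdm3a (2.92-fold), Bhlhe40 (2.51-fold) and Car9 (2.48-fold) higher in hiEGL2. On the authors' values Lox and Car9 were not called (adjusted p = 0.130 and 0.105). Lox is also on the fibroblast marker list. Glycolysis genes had 8 rises and no fall among 20 (camera adjusted p = 0.00111, adjusted p = 0.233 with an estimated correlation), led by Pdk1 (2.79-fold) and Ldha (2.34-fold). Immediate-early and heat-shock genes had 5 rises and no fall among 14 (camera adjusted p = 0.0159, adjusted p = 0.473 with an estimated correlation), with Zfp36 (3.87-fold), Junb (3.5-fold) and Dusp1 (2.05-fold) and no heat-shock gene among the rises. Klf4 was 2.35-fold higher in hiEGL2, Pou5f1, detected on 1 of 2 hiEGL2 arrays, was 1.74-fold lower, and Nanog differed by 0.02 ± 0.09 (SE, adjusted p = 0.906).

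Between these lines 2713 genes were called, 1263 higher and 1450 lower in hiEGL2, 659 of them by at least 2-fold. Both hiEGL2 arrays were dimmer before normalization, with mean signals of 173 and 168 against 251 and 257 on the hiEGL1 arrays. Line and signal level thus coincide in this comparison. Pluripotency lists were not called, with 0 higher and 5 lower of 15 core genes (camera adjusted p = 0.0885, adjusted p = 0.473 with an estimated correlation) and 3 higher and 6 lower of 18 naive genes (camera adjusted p = 0.326, adjusted p = 0.473 with an estimated correlation). The core list was called lower without the filter (adjusted p = 0.0131) and without hiEGL2 replicate 2 (adjusted p = 0.0412). Counts adjusted over the list alone differed for core pluripotency (0 higher, 6 lower), naive pluripotency (3 higher, 8 lower), later germline (1 higher, 1 lower), HIF targets other than glycolysis (14 higher, 3 lower), DNA methylation and chromatin (7 higher, 4 lower), gonadal somatic cells (1 higher, 0 lower), fibroblast feeder cells (3 higher, 1 lower) and primitive endoderm and trophectoderm (8 higher, 1 lower). The count was 1597 without hiEGL1 replicate 1, 1574 without hiEGL1 replicate 2, 1756 without hiEGL2 replicate 1 and 1679 without hiEGL2 replicate 2, and 4447 when only the compared arrays were fitted. Without the quantile step, where the median of all genes was 0.29, 63.1% of called genes were higher in hiEGL2 in place of 46.6%, and the stress list's call ended without hiEGL2 replicate 1 (adjusted p = 0.0660).

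Setting hiEGL against PGC11.5 asked how the lines differ from germ cells still in the embryo. The chemokine gene Cxcl1 was at least 256-fold higher in hiEGL (13.86 ± 0.46 in hiEGL and 4.36 ± 0.00 in PGC11.5, SD, n = 4 and 2, adjusted p = 6.61e-13), with rises also of Igfbp7 (at least 148-fold), Aebp1 (at least 127-fold), Timp3 (at least 81.5-fold), Col6a1 (at least 82.2-fold) and Eno2 (at least 81.2-fold). Axl, which encodes a receptor kinase, was 181-fold higher, and the matrix gene Bgn, detected on 1 of 2 PGC11.5 arrays, was 198-fold higher. The largest falls included H2ac7 (at least 187-fold), H2ac12 (at least 169-fold), H2ac15 (at least 202-fold), Rps7 (at least 229.9-fold), Rpl24 (at least 173-fold), Snrpg (at least 95.0-fold) and Snrpd1 (at least 86.9-fold), and the embryonic globin gene Hbb-y was at least 78.2-fold lower. Hbb-y stood at 14.37 on PGC11.5 replicate 1 and 10.09 on replicate 2. The largest adjusted p among all these genes was 9.99e-06 by limma's test.

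Later germline genes were lower in hiEGL than in PGC11.5, whereas early PGC genes were not called as a list. Of the later germline list, 3 rose and 10 fell of 14 measured (camera adjusted p = 0.0350, adjusted p = 0.439 with an estimated correlation), and Dazl (at least 36.9-fold), Asz1 (at least 13.5-fold) and Mov10l1 (at least 4.84-fold) fell. Early PGC genes had 4 higher and 7 lower of 11 (camera adjusted p = 0.333, adjusted p = 0.508 with an estimated correlation) and were called lower with the mean of probes (adjusted p = 0.0389). Dppa3 was 44.1-fold lower, Nanos3, detected on 2 of 4 hiEGL arrays, was 6.15-fold lower, and Ddx4 was at least 3.21-fold lower. Pou5f1, detected on 3 of 4 hiEGL arrays, was 52.5-fold lower in hiEGL, where Klf4 was at least 9.49-fold and Nanog 2.07-fold higher, and Sox2 differed by 0.01 ± 0.25 (SE, adjusted p = 0.963) with 1 of 4 and 1 of 2 arrays detecting it, and by -2.33 with the mean of its probes. HIF targets outside glycolysis had 20 rises and 7 falls among 29 (camera adjusted p = 0.0406, adjusted p = 0.439 with an estimated correlation). These included Ndrg1 (at least 28.2-fold), Lox (at least 34.0-fold, also a fibroblast marker) and Car9 (at least 13-fold), all higher. Vegfa, detected on 1 of 2 PGC11.5 arrays, was 37.8-fold higher, and Hif1a, not detected in hiEGL, was at least 1.68-fold lower. Oxidative phosphorylation genes had 10 rises and 30 falls among 44 (camera adjusted p = 0.000124, adjusted p = 0.439 with an estimated correlation), led by Uqcrh (at least 73.5-fold) and Atp5pb (at least 28.2-fold). Cell cycle genes had 7 rises and 14 falls among 26 (camera adjusted p = 0.0314, adjusted p = 0.439 with an estimated correlation), led by Mcm7 (at least 20.1-fold) and Cdca8 (at least 20.2-fold). Fibroblast markers had 20 rises and no fall among 23 (camera adjusted p = 0.000124, adjusted p = 0.508 with an estimated correlation). Immediate-early and heat-shock genes had 12 rises and 1 fall among 14 (camera adjusted p = 0.0314, adjusted p = 0.508 with an estimated correlation). The fall was that of Hsp90aa1, by 0.97 on the log2 scale. Gonadal, blood and primitive endoderm marker lists were not called (adjusted p = 0.257, 0.333 and 0.0813). The last was called higher in 4 alternatives (adjusted p = 0.0222 without the filter, 0.0436 with the mean of probes, 0.0338 with the line as a random block and 0.0267 without PGC11.5 replicate 1), and the blood list without PGC11.5 replicate 1 (adjusted p = 0.0267).

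Calls numbered 6985 for hiEGL against PGC11.5, 4082 higher and 2903 lower in hiEGL, around a median log2 difference of all genes of 0.22. Opposite calls of a gene's probes made up 31.4% of pairs. Without the quantile step the median of all genes was -0.40 and 38.0% of called genes were higher in place of 58.4%. Adjusted over the list alone, the count differed for primitive endoderm and trophectoderm (11 higher, 1 lower). The HIF target call ended without PGC11.5 replicate 2 (adjusted p = 0.0732), with the strict filter (adjusted p = 0.0588) and without the quantile step (adjusted p = 0.0736, median 0.23 in place of 1.61). That of later germline genes ended without PGC11.5 replicate 2 (adjusted p = 0.125) and without the filter (adjusted p = 0.104), and that of cell cycle genes without the quantile step (adjusted p = 0.114).

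EG cells were compared with PGC11.5 in the same way, to set the conventionally derived cells against germ cells. Dnmt3l was at least 246-fold higher in EG (13.80 ± 0.08 in EG and 4.38 ± 0.03 in PGC11.5, SD, n = 2 and 2, adjusted p = 2.86e-12), and Upp1 (at least 94.5-fold), Hap1 (at least 71.8-fold) and Laptm5 (110.0-fold) rose too. H2ac7 (at least 203-fold), H2ac15 (at least 220.2-fold) and H2ac12 (at least 184-fold) fell, and Dppa3, a gene of germ cells and the early embryo, was at least 119.8-fold lower. Pou5f1 was 19.5-fold lower in EG, while Klf4 (at least 28.8-fold), Tdgf1 (at least 16-fold) and Nanog (4.58-fold) were higher. Sox2, detected on 1 of 2 PGC11.5 arrays, was 3.84-fold higher by 1 probe (log2 difference -1.31 with the mean of its probes), and Hif1a, not detected in EG, was at least 1.82-fold lower. Oxidative phosphorylation was the list called, with 14 rises and 28 falls among 44 (camera adjusted p = 0.00601, adjusted p = 0.371 with an estimated correlation), among them Uqcrh (at least 79.9-fold) and Atp5o (at least 12.9-fold). Glycolysis genes had 14 higher and 4 lower of 20 (camera adjusted p = 0.0844, adjusted p = 0.371 with an estimated correlation). Of the HIF targets outside glycolysis, 18 of 29 were higher in EG too and 5 lower, with a median of 0.67 (camera adjusted p = 0.126, adjusted p = 0.371 with an estimated correlation). Single targets were thus higher than PGC11.5 in EG too, but the list was not called there. Of all 9054 genes tested, 4012 were higher in EG. Later germline genes had 3 higher and 9 lower of 14 (camera adjusted p = 0.0844, adjusted p = 0.371 with an estimated correlation). Fibroblast markers had 16 higher and 2 lower of 23 with a median of 1.39 (camera adjusted p = 0.126, adjusted p = 0.711 with an estimated correlation), called higher without the filter (adjusted p = 0.0151) and without PGC11.5 replicate 1 (adjusted p = 0.00162), and the other marker lists were not called (adjusted p = 0.664, 0.455 and 0.759). Calls numbered 6558, 4012 higher and 2546 lower in EG, with a median log2 difference of all genes of 0.26 and opposite probe calls in 31.3% of pairs. Without the quantile step the median was -0.71 and 30.5% of calls were higher in place of 61.2%, with the line as a random block 4208 genes were called, and the oxidative phosphorylation call ended without the quantile step (adjusted p = 0.0727). Under that setting the glycolysis list was called instead (adjusted p = 0.00817), as it was without the filter (adjusted p = 0.00498), with the mean of probes (adjusted p = 0.0499) and without PGC11.5 replicate 1 (adjusted p = 0.0359). List counts differed when adjusted over the list alone for primed epiblast (7 higher, 4 lower) and primitive endoderm and trophectoderm (6 higher, 1 lower).

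Changes of hiEGL and of EG against the same PGC11.5 arrays were set side by side to ask whether both kinds of line left the germ cell profile alike. Across genes, which are not independent replicates, their log2 differences correlated at r = 0.775. In 100 simulations of unchanged groups the mean r was 0.578 and the highest 0.602. These gave all arrays of a gene the same spread, whereas the PGC11.5 replicates differed more than other pairs (SD of difference 0.692 against 0.170 to 0.232). The simulated r is thus no measure of what the shared PGC11.5 arrays alone would give. The covariance was 2.31, 2.29 above the simulated 0.0231, which rests on the same assumption. Genes higher than PGC11.5 in both numbered 3048, where 1809 would overlap if the lists were independent, genes lower in both 2105 (816 if independent), and 448 had opposite calls. Eno2, Ndrg1 and Hk2 were higher and H2ac7, H2ac12 and Uqcrh lower in both. Part of the overlap can come from the shared PGC11.5 arrays. With PGC11.5 replicate 1 for hiEGL and replicate 2 for EG, an alternative chosen after seeing the data, r was 0.749, and 0.667 the other way round. Both comparisons also cross the array divide, with opposite probe calls in 31.4% and 31.3% of pairs, and the simulations leave that shared difference out, so r does not tell it from a common departure from germ cells.

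Comparison with ESC asked how the lines differ from the reference pluripotent cells derived from the early embryo. In hiEGL, Cxcl1 (at least 419.6-fold) rose most (13.86 ± 0.46 in hiEGL and 4.66 ± 0.09 in ESC, SD, n = 4 and 4, adjusted p = 1.25e-13), with Axl (163-fold), Mmp2 (159-fold), Medag (at least 110.3-fold) and Aebp1 (139-fold) also higher. Spon2 and Igfbp4, each detected on 3 of 4 ESC arrays, were 285-fold and 231-fold higher. Lower in hiEGL were Rps7 (at least 269-fold), H2ac7 (at least 139.6-fold), Rpl24 (at least 185-fold), Rpl7a (at least 160.1-fold), Snrpg (at least 68.3-fold) and Nhp2 (at least 78.2-fold). Core pluripotency genes had 2 rises and 13 falls among 15 (camera adjusted p = 0.000641, adjusted p = 0.249 with an estimated correlation), with falls of Fgf4 (at least 4.36-fold) and Nanog (3.03-fold). Pou5f1, detected on 3 of 4 hiEGL arrays, was 65.3-fold lower and Sox2, detected on 1 of 4, 16.3-fold lower. Both Pou5f1 probes were dim in EG and hiEGL, at 6.80 and 6.52 for ILMN_1217100 against 11.52 in ESC. Naive genes had 1 rise and 16 falls among 18 (camera adjusted p = 0.000226, adjusted p = 0.0770 with an estimated correlation), including Jam2 (at least 19.4-fold), Zfp42 (at least 7.73-fold) and Klf2 (8.78-fold), and Esrrb fell by 0.48 on the log2 scale (adjusted p = 1.27e-05). Primed epiblast genes had 4 rises and 11 falls among 20 (camera adjusted p = 0.0361, adjusted p = 0.428 with an estimated correlation), led by Lefty2 (at least 19.3-fold), Dnmt3b (21.7-fold) and Lefty1 (13.5-fold).

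Oxidative phosphorylation genes had 6 rises and 37 falls among 44 in hiEGL against ESC (camera adjusted p = 1.26e-06, adjusted p = 0.2 with an estimated correlation), with Uqcrh (at least 58.9-fold), Uqcrb (at least 48.9-fold) and Atp5pb (at least 26.1-fold). Cell cycle genes had 5 rises and 18 falls among 26 (camera adjusted p = 0.00449, adjusted p = 0.131 with an estimated correlation). DNA methylation and chromatin genes had 3 rises and 16 falls among 20 (camera adjusted p = 0.000226, adjusted p = 0.131 with an estimated correlation). 2-cell-like genes had no rise and 5 falls among 6 (camera adjusted p = 0.0178, adjusted p = 0.249 with an estimated correlation). Falls included Birc5 (16.3-fold), Ezh2 (at least 22.5-fold) and Zscan4c (at least 7.90-fold). The Ezh2 value depended on the probe. Its probe ILMN_2988572, not detected in hiEGL, stood at 5.16 there against 6.24 in ESC and 6.94 in EG. HIF targets outside glycolysis had 17 higher and 7 lower of 29 and were not called as a list (camera adjusted p = 0.172, adjusted p = 0.371 with an estimated correlation), although P4ha2 (43.8-fold), Car9 (at least 21.3-fold), P4ha1 (at least 12.1-fold) and Vegfa (9.60-fold) rose. Hif1a, not detected in hiEGL, was at least 1.59-fold lower. Fibroblast markers had 20 rises and 1 fall among 23 (camera adjusted p = 0.000641, adjusted p = 0.428 with an estimated correlation). Blood, endothelium and macrophage markers had 9 rises and no fall among 14 (camera adjusted p = 0.0372, adjusted p = 0.428 with an estimated correlation). Immediate-early and heat-shock genes had 12 rises and 2 falls among 14 (camera adjusted p = 0.0450, adjusted p = 0.493 with an estimated correlation). Among these markers and genes, Timp2 (21.3-fold), Cd34 (at least 5.55-fold) and Ier3 (105-fold) rose. The 2 falls of the stress list were again heat-shock genes, Hsp90aa1 by 4.09 and Hspb1 by 2.20 on the log2 scale. Gonadal and primitive endoderm marker lists were not called (adjusted p = 0.188 and 0.125), the second of them except without ESCf replicate 2 (adjusted p = 0.0438). Calls numbered 7622, 4108 higher and 3514 lower in hiEGL, with a median of all genes of 0.11 (0.42 without the quantile step) and opposite probe calls in 20.6% of pairs. No list count differed when adjusted over the list alone. Without the quantile step the calls of the primed, blood, stress and 2-cell-like lists ended (adjusted p = 0.453, 0.0596, 0.0939 and 0.166), and so did those of the primed and stress lists with the mean of probes (adjusted p = 0.0808 and 0.0918). With the line as a random block the 2-cell-like and stress calls ended (adjusted p = 0.0538 and 0.0571). The stress list was also not called without hiEGL2 replicate 1 (adjusted p = 0.0606), hiEGL2 replicate 2 (adjusted p = 0.0561) or ESCf replicate 1 (adjusted p = 0.0505). Without ESCf replicate 1, and likewise without replicate 2, the 2-cell-like list kept 4 measured genes, too few for a test.

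EG cells against ESC gave the corresponding difference of the conventionally derived cells. Txnip, which encodes a thioredoxin-binding protein and was detected on 2 of 4 ESC arrays, was 43.8-fold higher in EG (10.71 ± 0.11 in EG and 5.26 ± 0.38 in ESC, SD, n = 2 and 4, adjusted p = 8.53e-11). Ifi27, detected on 3 of 4 ESC arrays, was 29.6-fold higher, and Ahcy and Zfp763, each detected on 2 of 4, were 18.5-fold and 15.9-fold higher. The largest falls were H2ac7 (at least 152-fold), Rpl7a (at least 174-fold), H2ac15 (at least 142-fold) and H2ac12 (at least 112-fold). Pou5f1 was 24.3-fold lower, Esrrb 3.47-fold and Klf4 1.85-fold higher (log2 difference -1.51 with the mean of its probes), and Nanog fell by 0.46 on the log2 scale (adjusted p = 0.000526). Oxidative phosphorylation genes had 8 rises and 33 falls among 44 (camera adjusted p = 1.53e-06, adjusted p = 0.583 with an estimated correlation), with Uqcrh (at least 64.1-fold) and Uqcrb (34.6-fold). Primed epiblast genes had 3 rises and 12 falls among 20 (camera adjusted p = 0.0442, adjusted p = 0.601 with an estimated correlation), led by Nodal (at least 4.68-fold) and Lefty2 (4.18-fold). Naive genes had 6 higher and 6 lower of 18 (camera adjusted p = 0.622, adjusted p = 0.651 with an estimated correlation), with a median of 0.03 and a mean of -0.18 that differed in sign. Of the HIF targets outside glycolysis, 14 of 29 were higher in EG and 5 lower (camera adjusted p = 0.622, adjusted p = 0.781 with an estimated correlation). Fibroblast markers had 13 higher and 5 lower of 23 with a median of 0.95 (camera adjusted p = 0.622, adjusted p = 0.841 with an estimated correlation), and the remaining marker lists were not called (adjusted p = 0.724, 0.704 and 0.622). Calls numbered 6599, 3969 higher and 2630 lower in EG, with a median of all genes of 0.21 and opposite probe calls in 25.2% of pairs. When adjusted over the list alone, counts differed for HIF targets other than glycolysis (14 higher, 4 lower) and gonadal somatic cells (3 higher, 3 lower). With the line as a random block 3916 genes were called, and the primed list's call ended under 5 settings (adjusted p up to 0.280) and without EG replicate 1 (adjusted p = 0.0529) or EG replicate 2 (adjusted p = 0.0733).

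EpiSC, which represent a later and primed form of pluripotency, were the last reference for the hypoxia-derived lines. Genes of the primed epiblast were far lower in hiEGL, with Otx2 (at least 24.3-fold), Fgf5 (at least 9.68-fold), Fgf8 (at least 10.8-fold), Lefty1 (36.0-fold) and Dnmt3b (34.6-fold), and 19 of 20 members of that list fell while 1 rose (camera adjusted p = 6.16e-07, adjusted p = 0.277 with an estimated correlation). Otx2 stood at 4.41 ± 0.10 in hiEGL and 10.54 ± 0.16 in EpiSC (SD, n = 4 and 2, adjusted p = 1.68e-08). Naive genes had 11 rises and 3 falls among 18 (camera adjusted p = 0.0261, adjusted p = 0.277 with an estimated correlation), with Esrrb (62.0-fold), Tcl1 (at least 26.7-fold), Klf4 (14.9-fold) and Dppa5a (13.2-fold). Early PGC genes had 8 rises and 2 falls among 11 (camera adjusted p = 0.0261, adjusted p = 0.277 with an estimated correlation). Later germline genes had 10 rises and no fall among 14 (camera adjusted p = 0.0261, adjusted p = 0.277 with an estimated correlation). These included Tfap2c (75.2-fold), Dnd1 (5.82-fold), Tdrd12 (15.8-fold) and Piwil2 (at least 8.76-fold). Pou5f1, detected on 3 of 4 hiEGL arrays, was 65.7-fold lower in hiEGL and Nanog rose by 0.32 ± 0.08 (SE, adjusted p = 0.00438), a call that ended without EpiE3 (adjusted p = 0.230). Sox2, detected on 1 of 4 hiEGL arrays, differed by 0.40 ± 0.25 (SE, adjusted p = 0.170), and by -1.76 with the mean of its probes. The largest rises were Rhox9 (at least 299-fold), Cxcl1 (401-fold), Spon2 (349-fold), Axl (233-fold) and Igfbp7 (232-fold), and the largest falls H2ac7 (at least 171-fold), Rps7 (at least 259.9-fold), H2ac12 (at least 168-fold), H2ac15 (at least 193-fold) and Trh (at least 257-fold).

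Glycolysis genes had 4 rises and 14 falls among 20 in hiEGL against EpiSC (camera adjusted p = 0.0279, adjusted p = 0.277 with an estimated correlation), with Aldoc (9.38-fold) and Slc16a3 (at least 2.67-fold) down and Eno2 (35.3-fold) up. HIF targets outside glycolysis had 15 higher and 13 lower of 29 (camera adjusted p = 0.949, adjusted p = 0.953 with an estimated correlation). They ran from Lox (at least 63.7-fold, also a fibroblast marker) and P4ha2 (27.5-fold) to Ddit4 (14.5-fold), the last of which fell. Oxidative phosphorylation genes had 9 rises and 30 falls among 44 (camera adjusted p = 0.000404, adjusted p = 0.277 with an estimated correlation). Cell cycle genes had 8 rises and 14 falls among 26 (camera adjusted p = 0.0395, adjusted p = 0.277 with an estimated correlation). DNA methylation and chromatin genes had 6 rises and 13 falls among 20 (camera adjusted p = 0.0285, adjusted p = 0.277 with an estimated correlation). Markers of other cells were higher in hiEGL, with 20 rises and 1 fall among 23 fibroblast markers (camera adjusted p = 0.000215, adjusted p = 0.390 with an estimated correlation). Primitive endoderm and trophectoderm markers had 12 rises and 1 fall among 18 (camera adjusted p = 0.0279, adjusted p = 0.281 with an estimated correlation). Blood, endothelium and macrophage markers had 9 rises and 1 fall among 14 (camera adjusted p = 0.0323, adjusted p = 0.431 with an estimated correlation). Also higher were 13 of 14 immediate-early and heat-shock genes (camera adjusted p = 0.00312, adjusted p = 0.360 with an estimated correlation). Gonadal somatic markers were not called as a list (adjusted p = 0.326). Calls numbered 7119, 3918 higher and 3201 lower in hiEGL, with a median of all genes of 0.14 (0.38 without the quantile step) and opposite probe calls in 26.9% of pairs. The count of glycolysis genes was 5 higher and 14 lower when adjusted over the list alone. Without EpiE3 the naive list's call ended (adjusted p = 0.104) and without EpiT9 the glycolysis call (adjusted p = 0.0582), and a fit to only the compared arrays lost 4 further lists (adjusted p up to 0.0800). The cell cycle call also ended on the authors' values (adjusted p = 0.0511) and the blood marker call without the quantile step (adjusted p = 0.0518).

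ESCf and ESCm were compared with each other as a check of line differences on one side of the array divide. The X-linked genes Xlr4a and Fmr1nb were 30.6-fold and 21.3-fold higher in ESCf (Xlr4a 11.77 ± 0.00 in ESCf and 6.84 ± 0.14 in ESCm, SD, n = 2 and 2, adjusted p = 1.26e-09), followed by Tcstv3 (15.6-fold) and Rcsd1 (at least 9.27-fold). The Y-linked gene Eif2s3y was at least 13.6-fold lower in ESCf (-4.61 ± 0.28 on the log2 scale, SE, adjusted p = 8.24e-06), followed by Ivns1abp (6.42-fold), Dusp4 (4.46-fold) and Rgcc (4.15-fold), and Xist was below background in both. Eif2s3y and Xist belong to the sex-linked list, of which 3 genes were measured, too few for a test. The 2-cell-like list had 5 rises and 1 fall among 6 (camera adjusted p = 5.88e-05, adjusted p = 0.199 with an estimated correlation), with Tcstv1 (at least 8.95-fold) and Zscan4c (5.92-fold). Oxidative phosphorylation genes had 13 rises and 1 fall among 44 with a median of 0.23 (camera adjusted p = 2.83e-05, adjusted p = 0.390 with an estimated correlation). Later germline genes had 4 rises and 1 fall among 14 (camera adjusted p = 0.00669, adjusted p = 0.390 with an estimated correlation). These included Smc1b (at least 3.89-fold) and Dazl (3.76-fold). Pou5f1 and Nanog differed by 0.22 ± 0.13 and 0.11 ± 0.09 (SE, adjusted p = 0.288 and 0.508).

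Calls for ESCf against ESCm numbered 1747, 924 higher and 823 lower in ESCf, 374 of them by at least 2-fold. Counts of more lists differed when adjusted over the list alone, namely core pluripotency (1 higher, 5 lower), naive pluripotency (6 higher, 4 lower), primed epiblast (6 higher, 2 lower), later germline (6 higher, 1 lower), HIF targets other than glycolysis (5 higher, 7 lower), glycolysis (4 higher, 4 lower), oxidative phosphorylation (14 higher, 1 lower), cell cycle (4 higher, 5 lower) and fibroblast feeder cells (1 higher, 0 lower). The count was 850 without ESCm replicate 1, 852 without ESCm replicate 2, 926 without ESCf replicate 1, 960 without ESCf replicate 2 and 3030 with only the compared arrays fitted. The number of called lists, 3, was 2 without ESCf replicate 1 and also without replicate 2, since the 2-cell-like list then kept 4 measured genes, too few for a test.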

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

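Differences between the lines were tested as planned, whereas the tests of other explanations below were chosen only after the results were seen, except those of a further degree of the array difference, of a shared PGC11.5 or EpiSC profile and of regrouped arrays. HIF targets, glycolysis genes and immediate-early and heat-shock genes stood out because lines hiEGL1 and hiEGL2 differed from EG to different degrees. The median log2 difference hiEGL2 minus hiEGL1 was 0.45 for HIF targets other than glycolysis (camera adjusted p = 0.000318), 0.26 for glycolysis (adjusted p = 0.00111) and 0.81 for immediate-early and heat-shock genes (adjusted p = 0.0159), none of which was called with an estimated correlation (adjusted p = 0.118, 0.233 and 0.473). Against EG, the median of HIF targets was 0.34 in hiEGL1 and 0.74 in hiEGL2, and that of glycolysis genes -0.06 and 0.06. The cause of the difference between the lines was not tested, and the hiEGL2 arrays were also dimmer than the hiEGL1 arrays.

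For the shifts of hiEGL against EG, a lower share of pluripotent cells could have lowered all core pluripotency genes alike. The called log2 falls had an interquartile range of 0.809 around a median of -1.24. That range is above the bound written against this explanation. A further condition, not part of what was written, asked whether probe disagreement alone could give so wide a range. Of 10000 draws of probe disagreement, a share of 0.0735 was as wide as the 8 falls detected on all EG and hiEGL arrays. The test thus left it open for the core list. What was written against this explanation also named a gene falling far beyond that median. Dnmt3l did so at -8.15, and Tdgf1 of the core list at -3.44, among others. Dnmt3l lies outside the core list and was undetected in hiEGL1, and Tdgf1 is 1 gene read by 1 probe. What was written against a common fall was thus met, but probe disagreement could give such a spread, so the question stays open for that list. RNA of other cells may account for part of the rises, since fibroblast markers rose by a median log2 of 1.98 and the lowest other marker list by 1.03, with Bgn at 13.86 against 11.19, Col6a1 at 12.21 against 7.28 and Timp2 at 12.06 against 8.97. Of the 23 fibroblast markers measured, 15 were detected on all EG arrays, 22 on all hiEGL arrays and 17 on all ESC arrays, so the list does not separate feeder cells from expression by the lines themselves. A further degree of the array difference was left open. The differences between probes of a gene correlated at -0.0927 across genes with those of EG against ESC, under the bound written against it. But EG enters both with opposite sign, and its replicates correlated at r = 0.997, which pulls this value down, so it cannot decide. On the first principal component EG stood at 36.5 and 36.4, the hiEGL arrays at 98.5 to 100 and the other arrays at -64.9 to -50.1. Culture in hypoxia, which the labels give, could raise HIF targets (median 0.475), but the glycolysis list had a median of -0.00770, so the test left it open.

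The divide between the EG and hiEGL arrays and the other 8 could come from expression or from RNA, amplification or labelling, and cell type and side of the divide coincide. Of 33 examined ribosomal protein probes detected on all 8 other arrays, 30 were detected on all 6 EG and hiEGL arrays and 2 on none. Their median log2 difference was -1.43. The 2 are fewer than the 5 written for this test as evidence against expression alone. But the selection of probes left out genes named Rpl with only a number, such as Rpl24. The count thus covers only part of the ribosomal protein genes and cannot decide. The SD of the disagreement between probes of a gene was at least 1.43 across the divide and at most 1.25 within a side, a ratio of 1.14. That ratio lies below the 1.2 written for this test as evidence against a technical cause, but it rests on ESC against PGC11.5 as the highest value within a side, and it was counted as undecided only after it was seen. The log2 differences of probes of a gene correlated across genes at as little as 0.372 across the divide and 0.517 within a side, so neither explanation can be excluded.

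PGC11.5 replicate 1 stood apart from replicate 2, with the embryonic globin genes Hba-x at 13.88 against 7.22 and Hbb-bh1 at 12.43 against 6.22 and the collagen gene Col1a1 at 8.17 against 4.45, while the germ cell genes Dppa3 and Dazl stood at 12.54 against 12.91 and 10.89 against 11.40. RNA of blood and somatic cells in replicate 1 is a possible explanation, with a median log2 difference of 5.45 for globins, 0.985 for fibroblast markers and 1.03 for blood, endothelium and macrophage markers, but gonadal somatic markers had only 0.0811, so the test left it open. Immediate-early and heat-shock genes also stood higher there, by 1.01. Of the 14 blood, endothelium and macrophage markers measured, 4 were detected on all ESC arrays. Both arrays carry the same labels, so no biological explanation was tested.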

How the results depend on the processing

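Every comparison kept genes past the threshold in every setting, and the median of 1 called list changed sign. That was primed epiblast for hiEGL against ESC, at -0.51 and, without the quantile step, 0.61, where the median of all genes was 0.42. Leaving out 1 array at a time gave 4698 to 5273 called genes for hiEGL against EG, 1574 to 1756 for hiEGL2 against hiEGL1, 6612 to 7377 for hiEGL against PGC11.5, 5867 to 7190 for EG against PGC11.5, 7252 to 7346 for hiEGL against ESC, 5629 to 6266 for EG against ESC, 6443 to 6830 for hiEGL against EpiSC and 850 to 960 for ESCf against ESCm. Where this leaves 1 array in a group, it is assumed to vary like the other groups. With the line as a random block, 2895 genes were called for hiEGL against EG, 4208 for EG against PGC11.5 and 3916 for EG against ESC, a block that cannot be fitted to hiEGL2 against hiEGL1 or ESCf against ESCm. A fit to only the compared arrays called 4447 genes for hiEGL2 against hiEGL1 and 3030 for ESCf against ESCm. At least a 2-fold difference, a stricter criterion by construction, left 2766 for hiEGL against EG, 659 for hiEGL2 against hiEGL1, 4352 for EG against PGC11.5, 4955 for hiEGL against ESC, 3719 for EG against ESC, 4692 for hiEGL against EpiSC and 374 for ESCf against ESCm.

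The number of called lists, 10 for hiEGL against ESC, was 6 without the quantile step. For EG against ESC, with 2, it was 4 without the quantile step, 1 with the strict filter, 5 with the mean of probes, 1 with the line as a random block, 1 with only the compared arrays and 1 to 2 without 1 array. For hiEGL2 against hiEGL1, with 3, it was 6 without the filter and 2 to 5 without 1 array, and for EG against PGC11.5, with 1, it was 5 without the filter, 4 with the mean of probes and 1 to 3 without 1 array. The correlation of both lines' changes against PGC11.5, 0.775 across genes, was 0.779 on the authors' values, 0.725 without the quantile step, 0.779 without the filter, 0.749 and 0.667 with a separate PGC11.5 array for each, chosen after seeing the data, and 0.775 to 0.783 without 1 array. EG stayed the nearest cell type of all hiEGL arrays on the authors' values, without background correction, without the quantile step, without the filter, with the strict filter and without 1 array, the settings tried for it. Log2 differences changed sign without the quantile step for Hif1a in hiEGL against EG (0.65) and Sox2 in hiEGL against PGC11.5 (-0.78), with the mean of probes for Sox2 in hiEGL against PGC11.5 (-2.33), Sox2 in EG against PGC11.5 (-1.31), Klf4 in EG against ESC (-1.51) and Sox2 in hiEGL against EpiSC (-1.76) and Sox2 in hiEGL against PGC11.5 lay between -0.50 and 0.53 without 1 array. The median of all genes on the authors' values was 0.35 for hiEGL against PGC11.5, 0.44 for EG against PGC11.5 and 0.31 for EG against ESC. The cause was not tested for any of these changes.

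Replicate numbers did not pair arrays between groups, since 15 correlations of replicate differences across genes lay between -0.0270 and 0.0309. The number as a block changed no list call and gave 5576 called genes for hiEGL against EG. The chip as a block was not run, because the column names give no chip. Weights for the PGC11.5 arrays, chosen after seeing the data, gave 5781 called genes for hiEGL against PGC11.5 and 5419 for EG against PGC11.5. Signal over background limits what was seen of dim genes, as 29.8% to 45.4% of probes were detected per array, and genes below background, such as Hif1a in hiEGL and EG, have no measurable change.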

Other observations

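Comparisons among ESC, EpiSC and PGC11.5, which lie on the same side of the array divide, were chosen only after the data had been seen. So were the genes named here. Probes of a gene also disagreed on this side, with opposite calls in 14.4% of pairs for EpiSC against ESC, 21.9% for PGC11.5 against ESC and 8.12% for PGC11.5 against EpiSC. EpiSC had no rise and 16 falls of naive pluripotency genes among 18 (camera adjusted p = 3.07e-10, adjusted p = 0.00642 with an estimated correlation) against ESC, including lower Esrrb (5.49 against 11.93) and Klf4 (5.20 against 9.82) on the log2 scale. Primed epiblast genes had 17 rises and 1 fall among 20 (camera adjusted p = 7.45e-06, adjusted p = 0.127 with an estimated correlation), with higher Fgf5 (9.22 against 4.64) and Otx2 (10.54 against 5.95). Glycolysis genes had 14 rises and no fall among 20 (camera adjusted p = 0.000910, adjusted p = 0.0984 with an estimated correlation) and HIF targets 19 rises and 8 falls among 29 (camera adjusted p = 0.0173, adjusted p = 0.111 with an estimated correlation). Lower too were core pluripotency genes, with no rise and 13 falls among 15 (camera adjusted p = 5.00e-06, adjusted p = 0.0984 with an estimated correlation), early PGC genes, with 2 rises and 9 falls among 11 (camera adjusted p = 0.000820, adjusted p = 0.0984 with an estimated correlation), and later germline genes, with 1 rise and 9 falls among 14 (camera adjusted p = 0.00121, adjusted p = 0.0984 with an estimated correlation). So were 2-cell-like genes, with no rise and 6 falls among 6 (camera adjusted p = 0.00251, adjusted p = 0.0984 with an estimated correlation), and fibroblast markers, with 1 rise and 10 falls among 23 (camera adjusted p = 0.0399, adjusted p = 0.690 with an estimated correlation). DNA methylation and chromatin, signalling and oxidative phosphorylation lists were also called lower (camera adjusted p = 0.00815, 0.00891 and 0.0466), but not with an estimated correlation (adjusted p = 0.132, 0.0984 and 0.582). In all, 5692 genes differed, 3122 higher and 2570 lower in EpiSC.

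PGC11.5 had 9 rises and 3 falls of later germline genes among 14 (camera adjusted p = 0.0246, adjusted p = 0.349 with an estimated correlation) against ESC, with higher Dazl (11.15 against 6.24) and Ddx4 (7.62 against 4.84), and 11 rises and no fall among 14 (camera adjusted p = 2.17e-06, adjusted p = 0.0364 with an estimated correlation) against EpiSC. Early PGC genes had 7 rises and 3 falls among 11 (camera adjusted p = 0.154, adjusted p = 0.435 with an estimated correlation) against ESC and 9 rises and 1 fall among 11 (camera adjusted p = 6.34e-05, adjusted p = 0.0426 with an estimated correlation) against EpiSC, with higher Dppa3 (12.72 against 5.15) and Nanos3 (8.22 against 4.44). Glycolysis genes had 3 rises and 17 falls among 20 (camera adjusted p = 2.17e-06, adjusted p = 0.0364 with an estimated correlation) and HIF targets 1 rise and 18 falls among 29 (camera adjusted p = 5.61e-05, adjusted p = 0.0364 with an estimated correlation) in PGC11.5 against EpiSC, with lower Vegfa (5.76 against 8.42). Against ESC, glycolysis genes had 5 rises and 14 falls among 20 (camera adjusted p = 0.0111, adjusted p = 0.307 with an estimated correlation) and HIF targets 6 rises and 15 falls among 29 (camera adjusted p = 0.166, adjusted p = 0.415 with an estimated correlation). Core, naive, primed, chromatin and 2-cell-like lists were called lower than in ESC (adjusted p = 0.0111, 0.00936, 0.0246, 0.0111 and 0.0111), with fibroblast markers not called (adjusted p = 0.0746). None of these lists was called with an estimated correlation (adjusted p = 0.415, 0.176, 0.545, 0.307 and 0.307). Sox2 of the core list depended on the probe, at 5.80 against 9.84 in ESC for ILMN_1248711 and 9.07 against 8.87 for ILMN_2656102. Against EpiSC the naive list was called higher and the primed list lower (camera adjusted p = 6.34e-05 and 1.32e-07). With an estimated correlation the naive list stayed called (adjusted p = 0.0364) and the primed list did not (adjusted p = 0.105). Calls numbered 6198 against ESC, 3067 higher and 3131 lower in PGC11.5, and 5360 against EpiSC, 2426 higher and 2934 lower.

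Predictions written before the values were computed were that hiEGL keep part of the PGC11.5 profile or share part of the EpiSC profile. Across genes, which are not independent replicates, the log2 differences hiEGL minus EG correlated at 0.277 with PGC11.5 against ESC and at 0.289 with EpiSC against ESC. The values are alike, so they single out neither cell type. The real grouping of the 8 hiEGL and ESC arrays gave 7087 called genes and the highest of the other splits 1. The arrays come from 4 lines of near-identical pairs, which can be split in only 3 ways, too few for a share under 0.05.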
